A study of Mus musculus with 6 samples.

How the data were processed

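Total RNA from pooled carotid bodies was measured on Affymetrix Mouse 430 2.0 arrays, 3 for A/J and 3 for DBA/2J, per the labels and the series' design text. The labels' protocols give Trizol extraction and a small-sample labelling with repeated cDNA synthesis and in vitro transcription before hybridisation. Such amplification starts at the poly(A) tail and shortens the product, so probe sets far from the 3' end can read low. Each array is a pool of 18 to 21 mice, so the spread between arrays is that between pools, not between mice.

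The deposited values are linear intensity signals with 1 decimal, from 0.1 to 27051. The software that made them is not given in the sources used here. The 2%-trimmed mean of every array is 500.0, so the authors' values had been scaled to a common level before deposit. Median signals lay between 163.6 and 183, close enough by the limit set in advance to use the values without further normalization. No detection call for each probe set was used here. Whether a dim probe set is above background is therefore unknown, and folds against dim values depend on the pseudocount. Probe sets were named from GEO's platform annotation, updated through gene identifiers with a RefSeq table (assembly GRCm38.p6) that was used for names and for which genes neighbour each other. Of 45101 probe sets, 34945 name 1 gene, 932 several and 9160 are not listed there and are unnamed here; 34741 of those with 1 gene matched the RefSeq table. Of the genes fixed for naming, 3 had no probe set named here.

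The values were analysed in R 4.3.3 with limma 3.58.1 and drawn with matplotlib 3.10.9. The 64 Affymetrix control probe sets were left out. Values were transformed as log2(signal + 16), and the upper 60% of probe sets by mean log2 value over the 6 arrays were kept (27022). The contrast DBA/2J minus A/J was fitted with lmFit and eBayes with an intensity trend, two-sided, with no covariate, and p was adjusted by Benjamini-Hochberg at a threshold of 0.05. For genes, the probe set with the highest mean among those that name that gene alone stood for the gene (13006 genes), and 4613 kept probe sets without a single gene name entered only the counts of probe sets. The series states a rule of 6 of 9 pairwise comparisons, 1.5-fold and a p under 0.05. The calls and the test behind it are not given in the sources used here, and fold per array pair and the unadjusted limma p stand in. Gene lists (38, each with at least 5 measured genes) were written before the data were examined, as were the main tests and the rule for naming genes. Some tests of the closing part were chosen later, as stated there. The lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. An estimated correlation and fry were alternatives; camera and the estimated correlation compare a list with the other genes, and fry asks whether its genes move one way on balance.

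The named genes are, to begin with, the 10 called genes with the largest log2 difference in each direction whose arrays did not overlap between strains. Then come up to 4 called members of each list with the smallest adjusted p, and a fixed set of carotid body genes and label checks. This gave 96 genes, of which 82 were called. Genes named outside the rule, in the closing part, were chosen after their values were seen.

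The procedure was tested on simulated data for the same comparison, with 27022 probe sets, their real means and the spread estimated by limma. With 200 changed probe sets, 9% of those changed 2-fold and 85% of those changed 4-fold were called, with 4 false calls among 98 calls. With 800 changed, 33.5% and 91.75% were called, with 33 false calls among 534.

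The alternatives were quantile normalization, scaling to one median, pseudocounts of 1 and 64, no filter and the upper 40% of probe sets, no intensity trend, array weights, the mean of all probe sets of a gene, leaving out each array in turn, and fits that use a number shared in the titles of some arrays. Added after seeing the data were fits without A/J arrays 1 and 3, without the arrays numbered 2, and with each array's mean of the skeletal muscle list as a covariate. List tests under the random block and the covariate used the ranked form of camera on the moderated statistics.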

Results

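Gene expression was measured in the carotid body, the small chemosensory organ at the fork of the carotid artery whose type I (glomus) cells sense low oxygen. Carotid bodies came from male mice of the inbred strains A/J and DBA/2J at 28 days of age. Each array was hybridised with RNA pooled from many animals. The 3 A/J pools held 40, 42 and 38 carotid bodies from 20, 21 and 19 mice, and the 3 DBA/2J pools held 38, 36 and 38 carotid bodies from 19, 18 and 19 mice. The question was which genes differ between the carotid bodies of these strains, which are known to differ in the size of the organ and in the breathing response to hypoxia. The 6 arrays held 45101 probe sets each, and their median signals lay between 163.6 (DBA/2J array 3) and 183 (DBA/2J array 2). Pearson correlations of log2 values across probe sets, which are not independent replicates, ran from 0.904 to 0.959 within a strain and from 0.878 to 0.924 between strains. These ranges overlap. DBA/2J array 2 correlated at 0.932 and 0.904 with DBA/2J arrays 1 and 3, and at 0.921 with A/J array 3. The number of arrays, 3 per strain, limits the precision of every value below, and all log2 differences are DBA/2J minus A/J on the log2(signal + 16) scale.

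The strains differed most in genes of contractile muscle, which were high in the A/J pools, while single genes of varied function were high in the DBA/2J pools. Mcpt2, a mast cell protease, had a mean signal of 186 ± 71.6 in A/J and 5743 ± 1139 in DBA/2J (SD, n = 3 arrays), the largest rise among called genes. Stab2, a scavenger receptor of sinusoidal endothelium, rose from 143 ± 8.64 to 1590 ± 184, and Scnn1b, a subunit of the epithelial sodium channel, rose from 290 ± 103 to 2587 ± 444. At the other end, Tnnc2, the troponin C of fast skeletal muscle, had 12447 ± 2463 in A/J and 97.6 ± 98.9 in DBA/2J, and Myh4, a fast myosin heavy chain, had 6627 ± 2485 and 48.6 ± 48.6. The remaining leading genes on the higher side were Cldn34c1, H2-Ea, Serpina1b, Lefty1, Slc35d3, Insm1 and Cemip, with log2 differences of 3.94, 3.74, 3.45, 3.29, 3.28, 2.93 and 2.93. Another probe set of Cemip gave 0.40. The remaining leading genes on the lower side were Ckm, Myh1, Tnni2, Acta1, Mylpf, Mybpc2, Ckmt2 and Myot, with log2 differences from -6.34 (Ckm) to -5.55 (Myot), all of them expressed in skeletal muscle.

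Across the 27022 probe sets tested with limma, 883 passed an adjusted p of 0.05, of which 502 were higher and 381 lower in DBA/2J. All 883 also changed by at least 1.5-fold, the minimum the series states, the smallest absolute log2 difference among them being 0.70. Counted once per gene, 583 of 13006 genes were called, 334 higher and 249 lower, and in each of the 583 the 3 DBA/2J values lay on one side of the 3 A/J values. Such separation was seen in 21.1% of all probe sets tested, where chance gives 10%. The series' own rule asked for 6 of 9 pairwise comparisons, a 1.5-fold change and a p under 0.05. With fold per array pair and the unadjusted limma p standing in for its calls and test, 2697 probe sets passed, 1403 higher and 1294 lower, and they included all 883. The count of 883 changed with the arrays used: it was 420, 640 and 395 without A/J arrays 1, 2 and 3. Without DBA/2J arrays 1, 2 and 3 it was 341, 1351 and 509. Fewer arrays also give less power, and most of the probe sets called without an array were among the 883. These were 407 of 420 without A/J array 1, 338 of 341 without DBA/2J array 1 and 806 of 1351 without DBA/2J array 2. The count was 0 with a number shared in some array titles as a fixed block, which leaves few degrees of freedom. It was 1 with each array's mean over the skeletal muscle list as a covariate, a score that nearly follows the strain, and 3007 with array weights, 1451 higher and 1556 lower. With that covariate the median SE over genes rose from 0.23 to 0.80. A turn of sign under it, given below for single genes, therefore does not tell genes that follow muscle from others. Of the 82 called genes named here, 41 were called without each array in turn.

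Genes of the type I cell were higher in the DBA/2J pools. Of 33 measured members of the type I cell list, 15 rose, 0 fell and 18 did not pass the test, with a median log2 difference of 0.88, and 22 rose when p was adjusted over the list alone. Chga, chromogranin A of the dense-core vesicle, rose from 732 ± 343 to 3585 ± 217 (SD, n = 3; log2 difference 2.37, SE 0.30, adjusted p = 0.0022). The vesicle proteins Chgb and Scg2 rose by log2 differences of 1.60 and 1.71, and Insm1, a transcription factor of neuroendocrine cells, by 2.93. Over the alternatives its median ran from 0.66 with array weights to 1.05 without A/J arrays 1 and 3, which carried the most skeletal muscle signal; the latter fit leaves a single A/J array, with the highest Gapdh 3' to 5' ratio (4.87). The list passed camera (adjusted p = 2.39e-15), while its adjusted p was 0.162 with an estimated correlation and 0.0186 with fry.

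**Figure D1:**
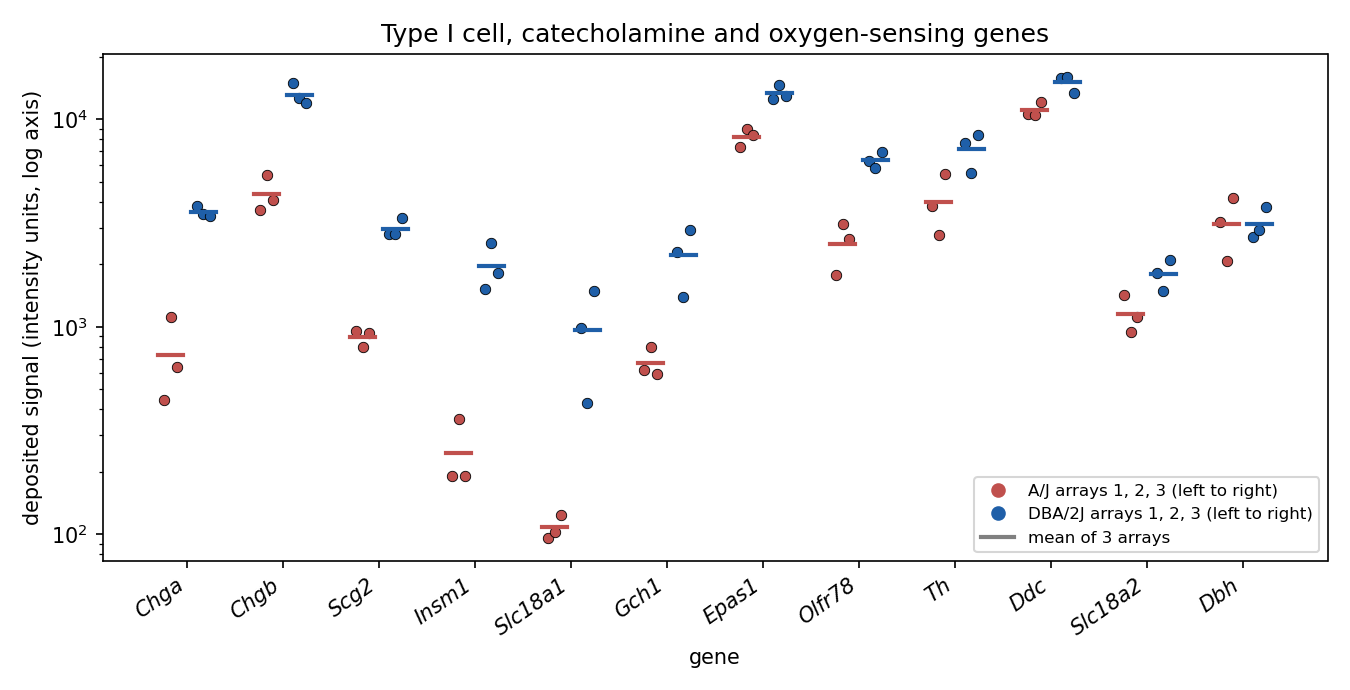
Deposited signals (intensity units, log axis) of 12 genes on each of the 6 arrays, A/J in red and DBA/2J in blue, with the mean of 3 arrays as a bar. Chga lies between 3414 and 3829 on the DBA/2J arrays and at most at 1112 on the A/J arrays, while the values of Dbh overlap between the strains.

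Genes that handle catecholamines were in part higher in DBA/2J. Of 16 measured genes of catecholamine synthesis, storage, uptake and breakdown, 4 rose, 0 fell and 12 did not pass the test, and 7 rose when adjusted over the list alone. The 4 were Slc18a1 (log2 difference 2.83), a vesicular monoamine transporter, Gch1 (1.65) and Pcbd1 (1.15), which make and recycle the tetrahydrobiopterin cofactor, and Cyb561 (0.97), the cytochrome of chromaffin granules. Slc18a1, Gch1 and Cyb561 are also members of the type I cell list. Gch1 turned to -0.41 (limma adjusted p = 0.869) with the muscle list mean as a covariate. Th, tyrosine hydroxylase, had 4001 ± 1344 in A/J and 7220 ± 1501 in DBA/2J, with a log2 difference of 0.88 and an adjusted p of 0.103. Ddc had a log2 difference of 0.44 (adjusted p = 0.117), with another probe set past the threshold at 1.86. Slc18a2 had 0.63 (adjusted p = 0.163), and Dbh, which turns dopamine into noradrenaline, had 0.04 (adjusted p = 0.966). The list passed camera (adjusted p = 0.0121), with an adjusted p of 0.540 with an estimated correlation and 0.116 with fry.

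Several genes of oxygen sensing were higher in DBA/2J, although the list as a whole was not shifted (camera adjusted p = 0.376). Of 29 measured members, 4 rose and 0 fell, and adjusted over the list alone 5 rose and 1 fell. Epas1, the hypoxia-inducible factor HIF-2 alpha, rose from 8237 ± 853 to 13354 ± 1124 (log2 difference 0.70, adjusted p = 0.0246). Olfr78, an olfactory receptor expressed in type I cells, rose from 2510 ± 681 to 6363 ± 577. With the muscle list mean as a covariate it was at -0.05 (limma adjusted p = 0.984). Arnt2 and Gucy1b1, a subunit of the nitric oxide receptor, had log2 differences of 1.60 and 1.46. For Gucy1b1 another probe set gave 0.43. Hif1a was 2342 ± 268 and 2301 ± 609, a difference well inside the spread between arrays. Of 25 hypoxia-inducible targets, 3 rose and 1 fell, and 3 rose and 3 fell adjusted over the list alone. That list was not shifted (camera adjusted p = 0.861), with a median log2 difference of -0.06, 11 members higher and 14 lower. The 3 that rose were Adm, the vasodilator peptide adrenomedullin (log2 difference 2.22), the carbonic anhydrase Car12 (2.19) and Pdk1 (1.10, other probe sets from -0.45 to 0.90). The hexokinase Hk2 fell by 1.46. Of these called targets, Adm alone turned, to -0.39 (limma adjusted p = 0.892), with the muscle list mean as a covariate. That fit is too imprecise to set Adm apart from the others.

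Ion channels and transmitter receptors showed a few large differences among many genes that did not pass. Chrna7, the alpha-7 nicotinic receptor, rose from 1477 ± 159 to 5263 ± 542 (adjusted p = 0.000555). P2ry12, an ADP receptor, rose from 679 ± 147 to 2773 ± 208. Of 44 potassium channel subunits, Kcnmb2 (log2 difference 1.77) and the channel-interacting Kcnip3 (1.21) rose and Kcnab1 fell by 0.88. Of these, Kcnmb2 alone turned, to -0.46 (limma adjusted p = 0.846), with the muscle list mean as a covariate. Kcnk3 at 0.18 and Kcnma1 at 0.10 did not pass. Adjusted over the list alone, 3 rose and 1 fell. Of 30 calcium, sodium and TRP channel subunits, the L-type calcium channel Cacna1d rose by 2.68, with another probe set at 0.22, and the sodium channel Scn7a fell by 0.74. Adjusted over the list alone, 4 rose and 1 fell. Of 11 cholinergic genes, Chrna7 rose and Bche, butyrylcholinesterase, fell by 0.94, both also when adjusted over the list alone. Chat at -0.06 and Chrna3 at 0.30 did not pass. Of 15 monoamine receptor and synthesis genes, Tph1, the enzyme of serotonin synthesis, rose by 1.69 and Hdc, which makes histamine, fell by 1.70, both also when adjusted over the list alone, and Drd2 was at 0.00. Of 25 ATP, adenosine, GABA and glutamate genes, P2ry12 and P2rx7 rose, the latter by 1.42 with other probe sets from 0.19 to 0.69, and adjusted over the list alone 2 rose and 2 fell. Of 27 neuropeptide and vasoactive peptide genes, 5 rose and 0 fell, among them Adm, the angiotensin receptors Agtr2 (1.35) and Agtr1a (1.10) and the enkephalin precursor Penk (1.14), and 5 rose and 2 fell adjusted over the list alone. None of these 6 lists was shifted by camera, the lowest adjusted p being 0.286.

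Signalling by bone morphogenetic proteins and the transcription factors of the neural crest, from which type I cells arise, leaned towards DBA/2J. Of 39 BMP and TGF-beta genes, 7 rose, 0 fell and 32 did not pass, and 9 rose when adjusted over the list alone. Gdf10 rose from 2946 ± 239 to 6423 ± 1446, Id3 from 1734 ± 143 to 4054 ± 503, and Id2, Bmp6 and Bmp7 had log2 differences of 1.07, 0.99 and 0.85. The list passed camera (adjusted p = 0.000842), with an adjusted p of 0.422 with an estimated correlation and 0.0429 with fry. Of 36 neural crest and pharyngeal arch factors, Phox2a (1.89), Hand2 (1.71) and Prrx1 (0.84, other probe sets from -0.75 to 0.77) rose, 0 fell and 33 did not pass, and 9 rose adjusted over the list alone. Phox2a and Hand2 are also members of the type I cell list, whose median was 0.88. Hand2 turned to -1.22 (limma adjusted p = 0.524) with the mean of the muscle list, whose median was -4.50, as a covariate. The neural crest list passed camera (adjusted p = 0.0314), with an adjusted p of 0.540 with an estimated correlation and 0.119 with fry. Of 40 neurotrophic and vascular growth factor genes, Ntrk2, the BDNF receptor, fell by 1.06 and 0 rose, also when adjusted over the list alone, and the list was not shifted (camera adjusted p = 0.298). Ret at -0.33 and Bdnf at 0.44 did not pass. Gdnf was too dim to be kept for the tests, with signals from 26.2 to 47.8 in A/J and from 182 to 354.9 in DBA/2J, and with no filter on dim probe sets its log2 difference was 2.32 (adjusted p = 0.00696).

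Skeletal muscle genes were far lower in the DBA/2J pools. Of 30 measured members of the muscle list, 25 fell, 0 rose and 5 did not pass, with a median log2 difference of -4.50, and adjusted over the list alone 26 fell and 1 rose. Ckm, the creatine kinase of muscle, had 11904 ± 4810 in A/J and 126 ± 42.5 in DBA/2J, and Pvalb, a calcium buffer of fast fibres, had 8648 ± 1768 and 292 ± 151. Another kept probe set of Ckm gave a log2 difference of -0.57 and was not called, against -6.34 here. The genes of the list made up 0.589%, 0.227% and 0.496% of the total signal on A/J arrays 1, 2 and 3, and 0.0183%, 0.0367% and 0.0167% on the DBA/2J arrays. On A/J array 2, with the least muscle signal of the A/J arrays, Ckm was still at 6404. The list passed camera (adjusted p = 4.81e-37), with an adjusted p of 0.317 with an estimated correlation and 0.0296 with fry.

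**Figure D2:**
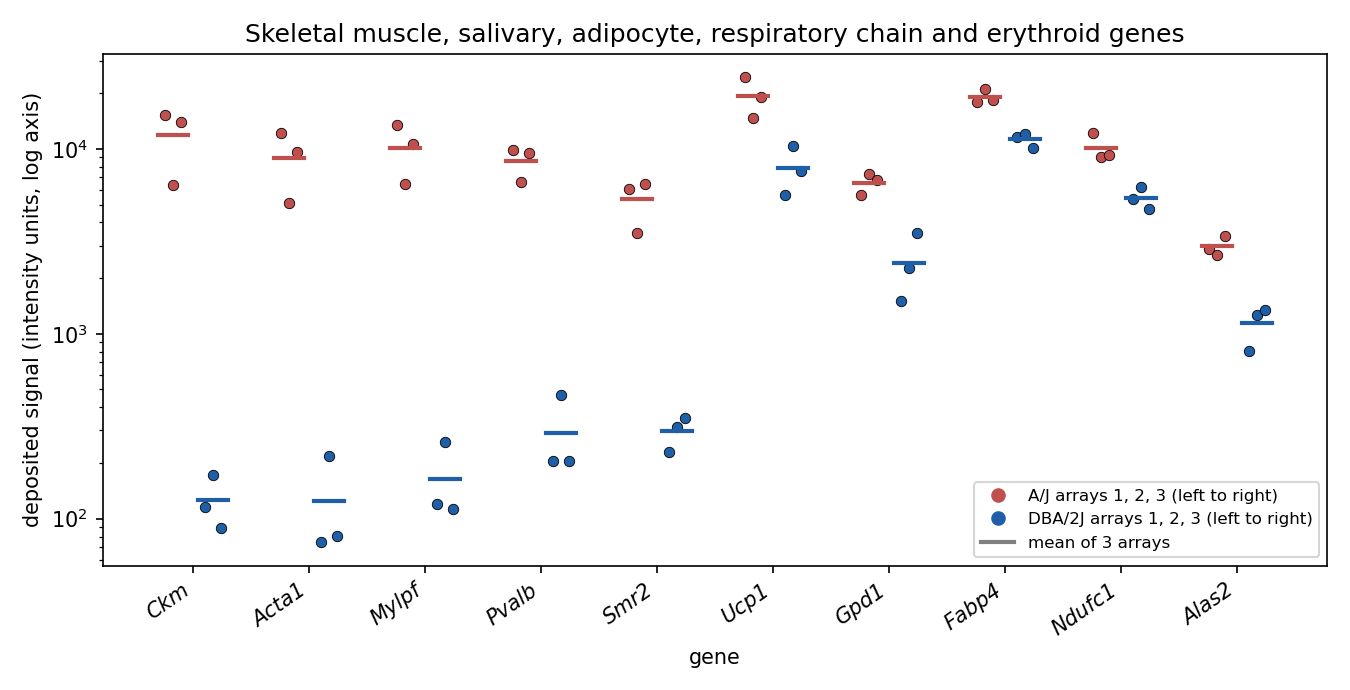
Deposited signals (intensity units, log axis) of 10 genes of skeletal muscle, salivary gland, adipocytes, the respiratory chain and erythroid cells on each of the 6 arrays, A/J in red and DBA/2J in blue, with the mean of 3 arrays as a bar. Ckm, by its brighter probe set, lies between 6404 and 15328 on the A/J arrays and between 89.0 and 172 on the DBA/2J arrays.

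Genes of fat, mitochondria and red cells were also lower in the DBA/2J pools, together with the muscle signal. Of 23 adipocyte genes, 4 fell and 0 rose, and 9 fell adjusted over the list alone. Ucp1, the uncoupling protein of brown fat, fell from 19361 ± 4856 to 7853 ± 2335, and Gpd1, Fabp4 and Cox7a1 fell by 1.51, 0.77 and 1.80 on the log2 scale. Among the A/J arrays, Ucp1 and Cox7a1 were lowest on array 2, which had the least muscle signal, while Gpd1 and Fabp4 were highest there. Ucp1 and Cox7a1 turned to 0.80 and 2.07 with the muscle list mean as a covariate, but neither passed (limma adjusted p = 0.631 and 0.357). That score nearly follows the strain, and the median SE over genes rose from 0.23 to 0.80 with it. Whether their fall is separate from the muscle signal is therefore not settled. The other probe sets of Gpd1 ran from -0.86 to 0.06, and none was called. The adipocyte genes made up 0.481% to 0.593% of the signal in A/J and 0.293% to 0.413% in DBA/2J. Of 66 subunits of the respiratory chain, Ndufc1, Uqcrq and Atp5pb fell, by 0.89, 0.99 and 0.59, and all 66 had negative log2 differences, with a median of -0.45. Another probe set of Uqcrq gave 0.01, and 14 subunits fell adjusted over the list alone. Of 7 erythroid genes, Alas2 and Hbb-b2 fell, with log2 differences of -1.40 and -1.30, and another probe set of Hbb-b2 gave -0.07, and 3 fell adjusted over the list alone. All 3 lists passed camera (adjusted p = 1.35e-10, 8.24e-16 and 0.000751), and none did with an estimated correlation (adjusted p = 0.422, 0.540 and 0.422) or with fry (0.118, 0.156 and 0.0511). With the muscle list mean as a covariate, the direction turned for the adipocyte genes (median 0.70, adjusted p = 0.00469) and the respiratory chain (median 0.75, adjusted p = 0.000389). Smr2, a salivary gland gene, had 5322 ± 1598 in A/J and 297 ± 61.9 in DBA/2J, the only called gene of 8 salivary markers, whose list did not pass camera (adjusted p = 0.0958). Adjusted over that list alone, 1 rose and 1 fell.

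Markers of glia were lower in DBA/2J, and those of most other cell types were not shifted. Of 22 type II and Schwann cell genes, Ugt8a, which makes the myelin lipid galactosylceramide, fell from 656 ± 101.2 to 128 ± 14.4, Scn7a and Cdh19 fell by 0.74 and 0.83, and 0 rose. Cdh19 alone of these turned, to 0.025 (limma adjusted p = 0.993), with the muscle list mean as a covariate. Adjusted over the glial list alone, 7 fell and 1 rose. The median was -0.50 and the camera adjusted p 1.76e-05, with an adjusted p of 0.317 with an estimated correlation and 0.0296 with fry. Of 24 smooth muscle and pericyte genes, Casq2, a calcium store protein also found in cardiac and slow skeletal muscle, fell by 1.66 and 0 rose, also when adjusted over the list alone. That list had a median of -0.22 and a camera adjusted p of 0.00892, but an adjusted p of 0.613 with an estimated correlation and 0.248 with fry. Of 28 fibroblast genes, Fbln2 and Fmod rose by 1.09 and 1.44, and of 11 mast cell and neutrophil genes Cma1, a mast cell chymase, rose by 1.44 and Hdc fell by 1.70. Adjusted over each list alone, 2 fibroblast genes rose, and 3 mast cell and neutrophil genes rose and 1 fell. Of 8 thyroid and parathyroid genes Slc26a4 rose by 1.47, and of 10 cartilage genes Hapln1 rose by 1.80, each also when adjusted over its list alone. Hapln1 turned to -1.01 (limma adjusted p = 0.720) with the muscle list mean as a covariate, while Slc26a4 kept its direction. These 4 lists did not pass camera, with adjusted p of 0.376, 0.244, 0.340 and 0.999. No member was called in 10 lists of 203 genes in all: ganglion neurons, sensory neurons, endothelium, macrophages, B cells, T cells and thymocytes, steroid-producing cells, immediate-early genes, cell division genes and interferon-stimulated genes. Of those 203 genes, 43 had an unadjusted limma p under 0.05. None of these 10 lists passed camera, the lowest adjusted p being 0.0631 for immediate-early genes, and 1 passed fry, the 7 sensory neuron genes (adjusted p = 0.0299). In 9 of the 10, 0 genes were called adjusted over the list alone, and of the interferon-stimulated genes 1 rose and 3 fell.

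Among the remaining lists, H2-Ea, a class II antigen-presenting chain, was the called member of 21 genes of the major histocompatibility complex region, rising from 401 ± 64.1 to 5922 ± 2522, and 3 rose adjusted over the list alone. Of 33 glutathione and detoxification genes, Cyp1b1 rose from 1958 ± 69.0 to 4725 ± 683 and Glo1 fell by 0.82, with other probe sets of Glo1 from -0.82 to 0.02, and the same numbers held adjusted over the list alone. Of 36 cytosolic ribosomal proteins, Rpl14 rose by 1.65, also adjusted over the list alone, while the median of the list was -0.09, turning to 0.03 after quantile normalization. Camera gave these 3 lists adjusted p of 0.0631, 0.247 and 0.292. In all, 10 of 38 lists were shifted, 4 higher and 6 lower in DBA/2J. With the correlation estimated per list 0 passed, 4 having an unadjusted p under 0.05, and fry called 6 lists, 4 of them among the 10. In 10 lists, none of them called, the median, the mean and the test differed in sign.

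**Figure D3:**
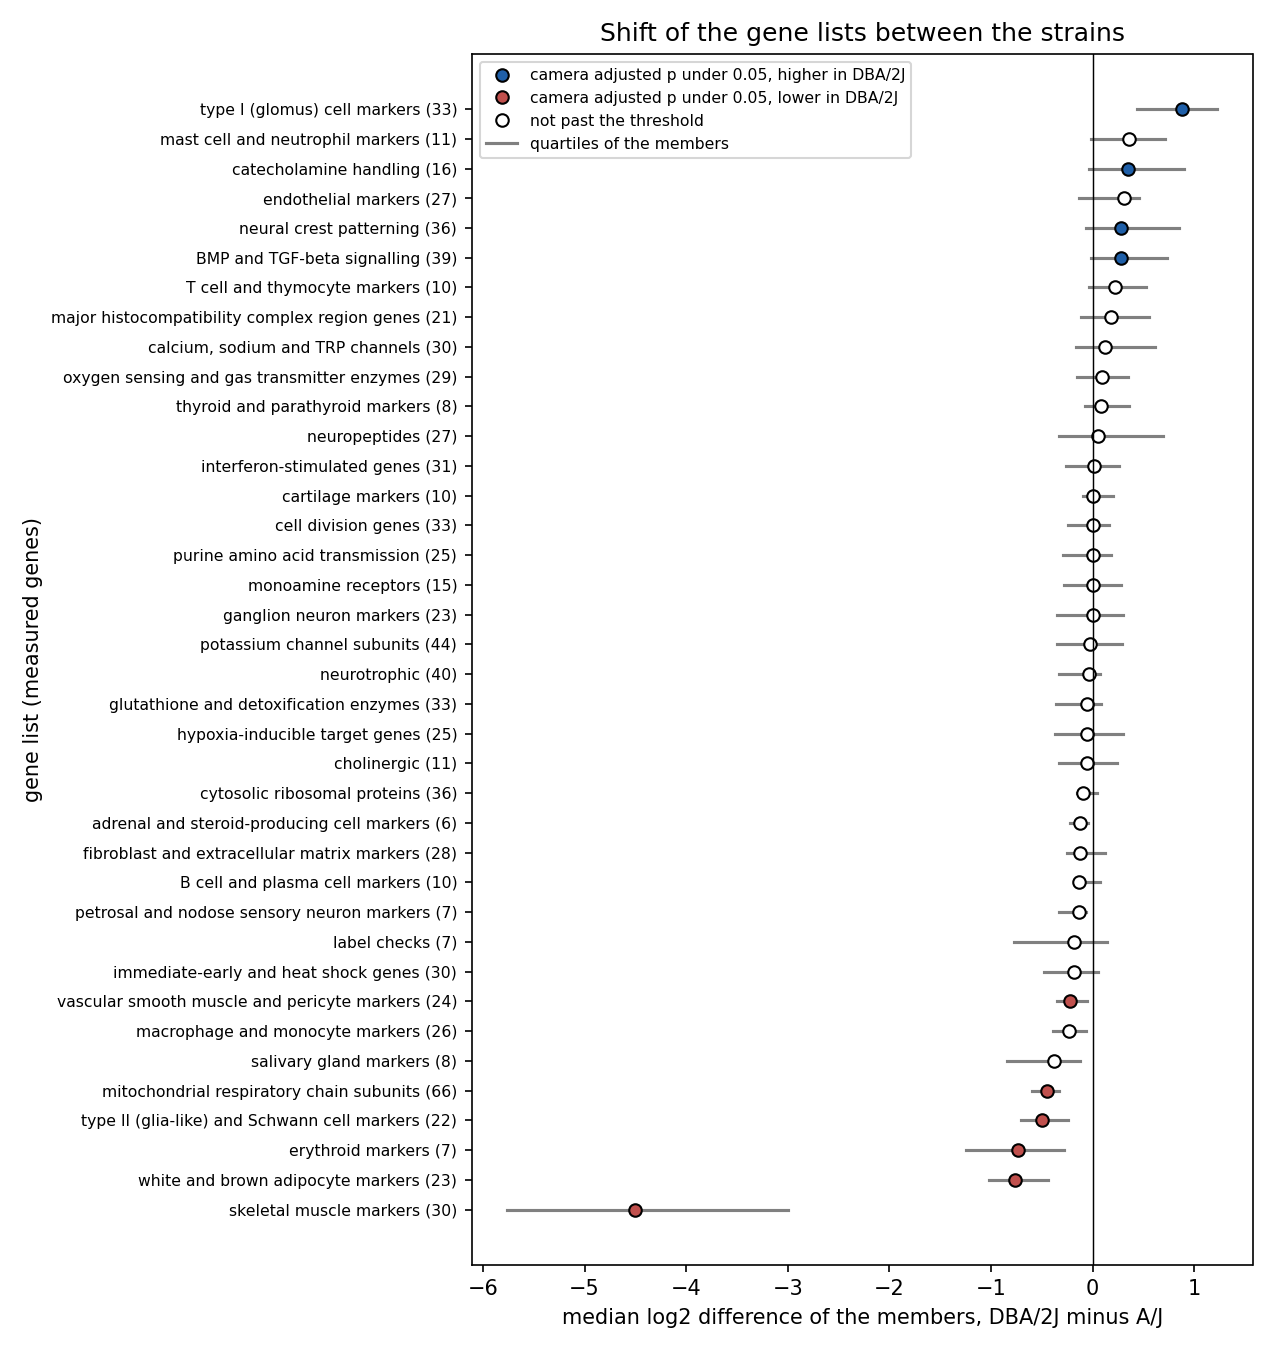
Median log2 difference (DBA/2J minus A/J) of the measured members of each of 38 gene lists, with lines from the lower to the upper quartile of the members; filled points passed camera at the preset correlation. Skeletal muscle markers lie at -4.50 and type I cell markers at 0.88.

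Genes that carry known variants in these strains followed the labels where they were bright enough. Gpnmb, in which DBA/2J carries a nonsense variant, had 726 ± 53.4 in A/J and 147 ± 65.7 in DBA/2J (adjusted p = 0.00413). Myo5a, the gene of the dilute coat colour of DBA/2J, had 774 ± 76.5 and 373 ± 51.0 (adjusted p = 0.0187). These 2 were the called members of 7 measured genes used to check the labels, and the only ones adjusted over the list alone. Their list did not pass camera (adjusted p = 0.125). Dysf, disrupted in A/J, was dim, with a mean of 59.1 ± 33.1 in A/J and 137 ± 33.3 in DBA/2J, and Klrd1, which is deleted in DBA/2J, had a log2 difference of -0.53 (adjusted p = 0.347). Xist, the transcript of the inactive X chromosome in females, had 3639 on DBA/2J array 3 and between 217 and 355 on the other arrays, and another probe set had 1768 against 4 to 38.4, although all pools are given as male.

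The ratio of 3' to 5' probe sets for Gapdh, which rises as RNA is degraded or shortened, was 1.74, 4.87 and 1.81 on A/J arrays 1, 2 and 3 and 2.50, 3.28 and 1.73 on the DBA/2J arrays. Without the arrays numbered 2 of both strains, which had the highest ratios, 2130 probe sets were called. Of 583 called genes, 233 had another kept probe set. For 70 of them another was called in the same direction, and for 56 none reached 0.25 times the log2 difference.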

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

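The alternatives chosen after seeing the data were the fits without A/J arrays 1 and 3, without both arrays numbered 2, and with the muscle score as a covariate. Of the 82 called genes named, 67 passed the threshold under all scaling, pseudocount, filter and trend alternatives, and 41 without each array in turn; 69 kept their direction in each of the 21 alternatives for single genes that gave them a value. Scaling moved the median of all probe sets by little (0.01 as deposited, 0.00 after quantile normalization, -0.01 with arrays scaled to one median). Signal near background limits the dim genes: the stated 3-part rule passed 4274 probe sets with no filter and 1781 in the upper 40%, because more or fewer were tested, and there the erythroid list had too few genes to test.

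With array weights, 3007 probe sets (1451 higher and 1556 lower in DBA/2J; 2880 by 1.5-fold or more) and 1832 genes were called. Leaving out each array in turn gave 341 to 1351 probe sets, the same at 1.5-fold or more, 230 to 914 genes, 2506 to 4030 by the 3-part rule, and 9 to 13 lists. Without A/J arrays 1 and 3 the numbers were 63 probe sets, 63 at 1.5-fold and 43 genes, with fewer arrays and a lone A/J array assumed to vary like the others. Without both arrays numbered 2 they were 2130, 2130, 1491 and, by the 3-part rule, 4322; the cause was not tested. The type I list median stayed between 0.66 and 1.05 in all alternatives. The muscle list median ran from -5.48 without both arrays numbered 2 to -3.14 without A/J arrays 1 and 3, apart from the covariate, and was -4.98 with a pseudocount of 1 and -3.93 with 64.

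The titles of A/J 2 and DBA/2J 2, and of A/J 3 and DBA/2J 3, share a number; the deviations of these arrays correlated at -0.26 and 0.04 across probe sets. The labels do not say what the number marks, and with 2 pairs these values do not show whether it may mark a shared day or step. With it as a fixed replicate block, limma called 0 probe sets, 0 at 1.5-fold and 0 genes (1955 probe sets at an unadjusted p under 0.05), and 1640 passed the 3-part rule; the block leaves few degrees of freedom. As a random block it called 848. In only the 4 arrays that share a number, 79 probe sets, 79 at 1.5-fold and 59 genes were called.

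With the correlation estimated per list, 0 lists passed; the type I list (median 0.88) and the muscle list (-4.50) then had adjusted p of 0.162 and 0.317. Fry called 6 lists.

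The muscle score nearly follows the strain, and with it as a covariate the median SE rose from 0.23 to 0.80. Then 1 probe set, 1 at 1.5-fold, 15 genes, 378 by the 3-part rule and 5 lists were called, with 2881 probe sets at an unadjusted p under 0.05. The list medians turned to 0.21 for skeletal muscle, which makes up the score, 0.70 for adipocytes and 0.75 for the respiratory chain, and the latter 2 lists passed in the opposite direction (adjusted p = 0.00469 and 0.000389). The type I list median was 0.89 with the covariate and passed (adjusted p = 0.0305). Log2 differences of single genes turned to -0.39 for Adm, 0.025 for Cdh19, 1.29 for Ckmt2, 2.07 for Cox7a1, -0.41 for Gch1, -1.22 for Hand2, -1.01 for Hapln1, -0.46 for Kcnmb2, 2.26 for Myot, 0.13 for Ndufc1, -0.049 for Olfr78, 0.80 for Ucp1 and 0.77 for Uqcrq, none of these genes past the threshold.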

Other observations

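The tests of array scaling, of dilution and of female mice below were chosen after the results they bear on were seen; the others were written before.

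Called genes sat side by side along the chromosomes in several places. Il20ra and Slc35d3, which neighbour each other, rose by log2 differences of 2.51 and 3.28, Adm and Ampd3 by 2.22 and 1.22, and Eml5 and Ttc8 by 1.74 and 1.67, while Gpam and Acsl5, enzymes of lipid synthesis, fell by 1.03 and 0.92. The genes of the mast cell proteases Cma1 and Mcpt2 are also neighbours and rose by 1.44 and 4.88. These pairs were picked after their values were seen. The hypothesis that shared haplotype blocks set the direction of neighbouring genes was tested by shuffling calls over 12943 ordered genes 10000 times, leaving out muscle list genes and pairs of adjacent genes that share their opening 3 letters. There were 20 adjacent pairs called in one direction (permutation p = 0.0166), and 18 after leaving out 2 more pairs of related genes, found on reading the list of pairs, against 11.7 ± 3.39 (SD) in shuffled orders (p = 0.0508). The latter p is just over the 0.05 set in advance, so the prediction for haplotype blocks was not met. The 2 pairs were left out of the real count but not of the shuffled ones, so these counts are not quite alike. The test therefore does not decide the question, and neighbours that are active in the same cells could give such pairs without any shared haplotype.

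Most called genes rested on single probe sets: 350 of the 583 had a single kept probe set, so no other could be set beside it. Psmd6, a proteasome subunit chosen after its values were seen, fell by 2.95 on the log2 scale with one probe set and had -0.15 with another. Among called genes, 25 had all their other probe sets on the opposite side of 0, while 70 had another called in the same direction. Sequence differences between the strains under the probes were not checked. Where probe sets disagreed, or a gene had a single kept probe set, the call is therefore a difference in signal. Whether it is also a difference in transcript level was not tested.

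Skeletal muscle genes were lower in DBA/2J than in A/J pools. The difference between the muscle list median and the median of all probe sets was -4.51. The arrays had been scaled to a common level before deposit, which set the median of all probe sets near 0 (0.01), so this difference is no separate test of scaling. The muscle list median was -4.45 after quantile normalization and -4.52 with arrays scaled to one median. As the array medians already lay between 163.6 and 183, rescaling could hardly move it, so these values are no separate test either. Differences in level that small fall far short of a log2 difference of -4.51. Muscle tissue in the A/J pools is a candidate explanation: of a further list of 35 muscle genes, which shares 0 genes with the main list, 24 were measured and 23 were lower in DBA/2J, with a median log2 difference of -0.99, but 41.7% were called lower, between the bounds of 20% and 50% set in advance. The abundant muscle transcripts were present, with Ckm at 11904 ± 4810, Acta1 at 8963 ± 3627 and Tnnc2 at 12447 ± 2463 in A/J, and 2 genes of the muscle list stand in other lists too. In the simulated data with 800 changed probe sets, 33.5% of those changed 2-fold were called, so the 41.7% cannot decide against muscle tissue. A strain difference in the tissue around the carotid body, or in its dissection, could each bring muscle tissue into the A/J pools. Which of them applies stays open and untested.

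Type I cell genes were higher in DBA/2J. The type I list median exceeded that of 125 endothelial, fibroblast, glial, macrophage and ganglion neuron markers by 1.02, but muscle and fat hold most of these cells too, which leaves that comparison undecided on dilution of the A/J pools. With the muscle score as a covariate the type I median was 0.89 (camera adjusted p = 0.0305 at the preset correlation). At an estimated correlation without the covariate the list had 0.162. The adipocyte and respiratory chain medians turned with the covariate. So did the muscle median, but its genes make up the score, so that turn was fixed by the fit. The score nearly follows the strain, the median SE over all genes was then 0.80, and the type I members Hand2 and Gch1 turned (-1.22 and -0.41). Without A/J arrays 1 and 3 the type I median was 1.05. The lone A/J array left still had 0.227% muscle signal, against 0.0367% or less in DBA/2J. Among the A/J arrays, Chga and Chgb were highest there (1112 and 5388), while Th and Scg2 were lowest (2760 and 803). The type I median thus did not shrink in either fit, but neither can exclude muscle as the whole cause, and dilution stays open. A common shift of all 33 genes, as a larger share of type I cells alone would give, is argued against by the SD of their log2 differences, 0.80 against a median SE of 0.24, and none of 10000 simulated draws from the standard errors spread as widely. Background signal and expression in other cells could also widen that spread. Such expression was not tested. The 18 genes that stand in other lists include members of functional lists such as catecholamine handling and oxygen sensing. All 33 measured genes lie outside the endothelial, fibroblast, glial, macrophage and ganglion neuron lists. A changed share of type I cells with other differences therefore stays open, as does an untested strain difference in expression per cell.

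Xist was high on DBA/2J array 3 alone, 12.6-fold over the mean of the other arrays by its brightest probe set, whose signal there may hold background, and 1768 against 4 to 38.4 by another. A pool of female mice only is argued against, since Y-linked Eif2s3y was at 99.3% of the mean of the other 5 arrays. Some female mice in the pool cannot be told apart from other causes: 0 of 3 Y-linked genes lay below the lowest of the other arrays by their brightest probe sets, another kept probe set of Kdm5d lay below it (105.1 against 120.9), and 1 mouse of 19 would lower them by only 5.26%, near the 4.08% spread of Eif2s3y between arrays. No biological explanation was tested.

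The 6 arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 883 probe sets (the highest other 34), 883 at 1.5-fold or more (34), 583 genes (10), 2697 probe sets by the 3-part rule (1788) and 10 lists (10). As many calls came from 1 of the 10 splits, the real one, for the probe sets, genes and 3-part rule, and from 3 of the 10 for the lists.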
